A study of Mus musculus with 336 samples.

How the data were processed

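Single blastomeres of mouse embryos at the 2-, 4- and 8-cell stage were profiled from wild-type embryos, embryos of dams given dioxin, and embryos labelled Ahr knockout. The table of read counts per gene and library was deposited by the authors and used as it stood: 24411 gene rows, 1615 of them 0 throughout, in 336 libraries, which are 328 blastomeres, 5 positive and 3 negative controls. Per the labels' protocols, libraries were made with SMART-seq v4 with 18 cycles of amplification and Nextera XT. Per the submitters' processing notes, bcl2fastq, STAR and edgeR were used with the build mm10; their versions, the role of edgeR, the counter, the annotation and any filter are not given in the sources used here. Per the labels, embryos were collected 46, 55 and 70 hours after hCG, wild-type dams received corn oil and dams of the labelled knockout are untreated. The dioxin dose is given per kg in one place (1 µg/kg) and per ml in another.

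The labels do not tie blastomeres to embryos, and the series text speaks of 8 embryos per group. Blastomeres are therefore not replicates, and counts were summed to 1 value per group, 9 sums in all. In 27 cases a date stood in place of a gene symbol and 2 names were repeated; none of these is named. In 42 columns a spreadsheet had turned the title code into a number, which was read back. The mitochondrially encoded list had 0 members in the table and was not analysed here. Blastomeres more than 3 median absolute deviations below the stage median in log reads or log genes were left out: 5 labelled-knockout, 3 wild-type and 1 dioxin at 8 cells, and 1 wild type at 4 cells. The 318 kept had 851200 to 2785260 reads (median 1539342.5). Kept blastomeres at 2, 4 and 8 cells numbered 16, 28 and 56 in wild type, 16, 34 and 62 in dioxin, and 16, 31 and 59 in the labelled knockout, with summed reads of 23627848, 41092794 and 105872298, of 19420938, 52456478 and 92262301, and of 22005396, 41353510 and 103722029. Positive controls had a median of 1393339 reads and negative controls of 259; neither was compared with blastomeres.

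Tests used edgeR quasi-likelihood fits on the 9 sums with additive condition and stage, TMM factors, filtering by expression (16225 genes) and Benjamini-Hochberg adjustment at 0.05. An SE given with an edgeR value is the absolute log2 fold change divided by the square root of the F statistic, not an SE that the model estimates. Stage served as the block for conditions and condition for stages, so p-values measure only the spread between sums that the additive model leaves over, not spread between embryos. No test was made within a stage; there a gene was counted by a rule of size, at least 2-fold apart in TMM-scaled CPM with a prior count of 2, at least 20 CPM in the higher sum and a read in at least 50% of that group's blastomeres. All CPM of sums are TMM-scaled. Intervals are 95% exact Poisson or binomial intervals and cover counting error only. The Poisson intervals take reads as independent and the binomial ones take blastomeres as independent. Neither covers amplification or spread between embryos, so intervals that do not overlap establish no difference between conditions. Shares of blastomeres with a read were also taken after thinning to 1e+06 reads, which 313 blastomeres reached, and variation between blastomeres was taken at that depth over genes with a mean of at least 10 reads in each condition. The limit that a count of 0 allows is 3 counts of the total. Summed list levels per blastomere are plain CPM, and were also divided by the TMM factor of their group, a choice made after the data were seen. Position was the median over genes of the 4-cell level between the 2-cell and the 8-cell level, over genes at least 4-fold apart between those stages in both other conditions.

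The 22 gene lists fixed at the start, 21 of them testable, were tested by limma's camera on voom values with a preset correlation of 0.01, again with an estimated correlation, and by fry. Every p of a list test is adjusted over the lists. They cover the AHR pathway, pluripotency, trophectoderm, Hippo and polarity, 2-cell-stage activation, oocyte-deposited transcripts, nucleolar genes, ribosomal proteins, respiratory chain, glycolysis, p53 targets, NRF2, heat shock, chromatin regulators, cell cycle, apoptosis, cumulus, oviduct, blood, sperm, and X and Y genes. Within a stage a list's median was placed among 10000 random lists matched in 25 expression bins, as description only. Genes within 20 Mb of Ahr on chromosome 12 were listed from the reference annotation of the build mm10.

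Genes named were Ahr, Pou5f1 and Cdx2 in every group; up to 12 per direction for each tested comparison, past the threshold, in the same direction in all 3 blocks, at an average log2 CPM of 4 or more and at least 2-fold; up to 8 per direction within a stage; and up to 4 members per list. Predicted genes and near-identical copies were counted but not named unless few others remained. Genes named beyond this rule were chosen after their values were seen.

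The grouping, tests, lists, rule of size, filters and most alternatives were chosen before the data were examined. The alternatives were DESeq2 size factors, the DESeq2 Wald test, limma-voom, other low-count and blastomere filters, thinning before summing, the mean CPM per blastomere, leaving out title codes that stand outside their group, no block, only the 6 sums compared, leaving out a stage or condition, other prior counts, levels and shares, single title codes, and other thinning depths. Leaving out 18 libraries far from their stage by correlation or genes detected, and taking wild-type 4-cell or dioxin 8-cell blastomeres of 1 title code, were chosen after the data were seen. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (version 1.17.8). The edgeR test was tested on simulated data for the labelled knockout against wild type only: of 50 genes changed at each of 2-, 4-, 8- and 16-fold it recovered 24, 64, 88 and 98%, with 8 false calls among 15561 genes and 1 call in a contrast left unchanged.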

Results

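The series addresses what the aryl hydrocarbon receptor does in the transcriptome of early mouse blastomeres, with Oct4 (Pou5f1) and Cdx2 as the lineage genes of interest. Counts of 328 single blastomeres came from wild-type, dioxin-exposed and labelled Ahr-knockout embryos at 2, 4 and 8 cells, of which 318 were kept. Because the labels do not tie blastomeres to embryos, each of the 9 condition and stage groups was used as 1 sum. Conditions were tested over the 3 stages and stages over the 3 conditions. The first number of the title code, which the labels do not explain, also changed with stage. All 2-cell blastomeres have code 1, and 8-cell blastomeres in the sums have code 2, 3 or 4. Within a condition the 4-cell and 8-cell sums share a code only through 1 wild-type 4-cell blastomere. Stage and code can therefore not be told apart at that step. Comparisons of conditions within 1 stage have no test and are given as values. Genes named outside the fixed rule for naming were chosen after their values were seen.

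Ahr itself was scarce and did not follow the knockout label at every stage. In wild-type blastomeres its sum stood at 4.39 counts per 1e+06 (CPM, 95% counting interval 3.67 to 5.23) at 2 cells, 1.35 (1.02 to 1.77) at 4 cells and 0.619 (0.451 to 0.828) at 8 cells. The dioxin sums were 2.20, 1.81 and 1.01 CPM. In the labelled Ahr knockout the sum was lowest of the conditions at 2 cells, 0.573 CPM from 19 reads (0.345 to 0.894), yet highest at 4 cells, 1.93 from 84 reads (1.54 to 2.39), and at 8 cells, 2.30 from 188 reads (1.98 to 2.65). The 19 reads lay in 4 of 16 blastomeres, with a maximum of 7.03 CPM. Judged by library read totals, that maximum lies in the library of title code 1G5, which thus holds most of the 19 reads. In that 2-cell group the library 1G5 had 22070 genes detected, against a group median of 11685. An Ahr read was found in 68.8, 25 and 14.3% of wild-type and in 25, 38.7 and 27.1% of labelled-knockout blastomeres at 2, 4 and 8 cells. Over the stages the tested Ahr difference between labelled knockout and wild type was 0.03 on the log2 scale (SE 0.90, edgeR adjusted p 0.994). Reads at 4 and 8 cells therefore go against a full loss of the transcript. No source used here gives the deleted part, and gene-level counts outside it check nothing. Every direction drawn for the labelled knockout below carries this limit.

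Pou5f1 was lower in the labelled knockout than in wild type at each stage: 36.8 against 70.2 CPM at 2 cells, 17.6 against 26.1 at 4 cells and 354.4 (350.4 to 358.6) against 638.1 (632.3 to 644.0) at 8 cells, with dioxin at 48.9, 28.7 and 492.3. The tested difference of −0.77 (SE 0.15) had an edgeR adjusted p of 0.679, so it did not pass, and that of dioxin was −0.25 (adjusted p 1). At equal depth the 8-cell mean per blastomere was 442.2 reads in wild type, 363.8 in dioxin and 273.1 in the labelled knockout, with SDs of 96.6, 98.9 and 114.9 between blastomeres. Cdx2 appeared at 8 cells: 20.1 (19.1 to 21.2) CPM in wild type, 17 (16.0 to 18.0) in dioxin and 5.59 (5.09 to 6.13) in the labelled knockout. A Cdx2 read was seen in 74.5, 78.7 and 49.2% of 8-cell blastomeres thinned to equal depth (intervals 61 to 85.3, 66.3 to 88.1 and 35.9 to 62.5%, 75, 77.4 and 50.8% unthinned). No 4-cell blastomere had one, which allows up to 10.7, 8.82 and 9.68% by 3 counts of the total (exact binomial upper limits 12.3, 10.3 and 11.2%), and at 2 cells the sums held 3, 4 and 24 reads. The 24 reads of the labelled knockout lay in 2 of 16 blastomeres, with a maximum of 14.06 CPM, so they show no difference between conditions.

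**Figure D1:**
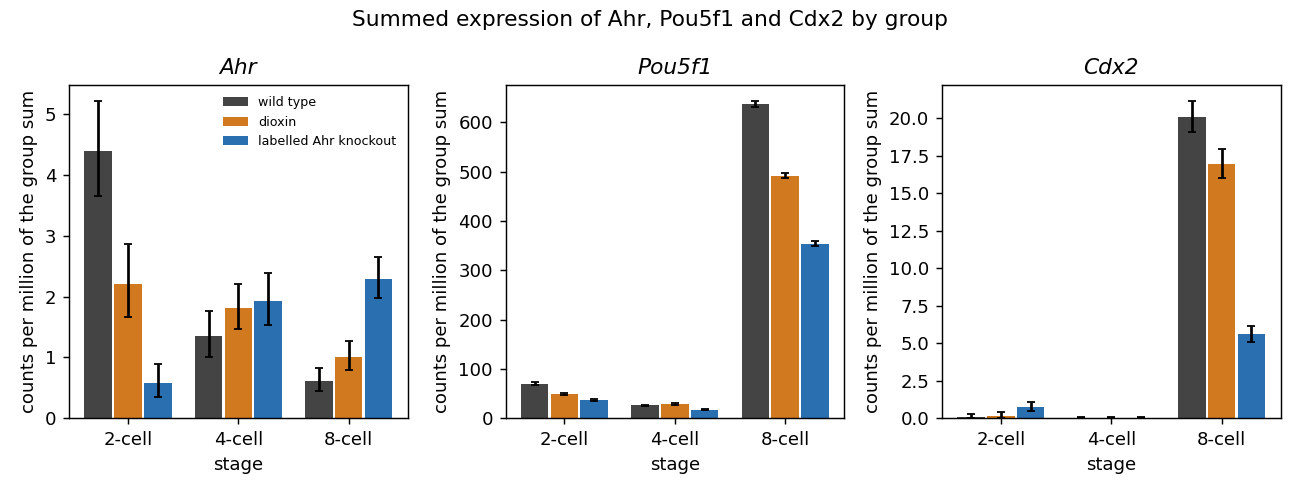
Bars are CPM of each group sum for Ahr, Pou5f1 and Cdx2 by stage, with 95% counting intervals. Ahr is lowest in the labelled knockout at 2 cells (0.573) and highest there at 8 cells (2.30), while Cdx2 is near 0 before 8 cells.

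From the 2-cell to the 4-cell stage, the machinery of protein synthesis and respiration rose while 2-cell-specific genes fell. Of 82 cytosolic ribosomal protein genes 79 rose and none fell, the same count adjusted over the list alone, with a median of 1.83 on the log2 scale; Rplp1 rose by 2.01. Nuclear respiratory chain genes rose in 70 of 82 cases with 1 fall (71 and 2 adjusted over the list alone, median 1.32), led by Atp5k (2.12) and Cox4i1 (1.55). Npm1 (2.07) and Ncl (1.50) were among 24 of 36 nucleolar and ribosome biogenesis genes that rose (26 adjusted over the list alone), and none fell. Zscan4d (−2.82), Zfp352 (−2.58) and Obox3 (−2.35) were among 18 of 27 genes of 2-cell-stage genome activation that fell, with 4 rises (19 and 4 adjusted over the list alone, median −2.09). Across all genes, 4165 passed: 2847 rose and 1318 fell, 4163 of them in the same direction in each condition, and 2854 at least 2-fold.

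The largest 4-cell rises under the naming rule were in Sycn (6.45, SE 1.07, adjusted p 0.00395), Prl3b1 (5.98), Smpdl3a (5.40, SE 0.40, adjusted p 0.000484), Vnn1 (5.05), Tdgf1 (4.84, SE 0.57, adjusted p 0.00102), Hes1 (4.47), Bhmt (4.22), Fabp3 (3.99), Cish (3.84), Fbp2 (3.81), Sox15 (3.81) and Cited1 (3.78). Tdgf1, a co-receptor of Nodal signalling, went from 1.72, 2.48 and 3.26 CPM in wild type, dioxin and labelled knockout to 79.1, 118.9 and 28.4, and Sox15 from 11, 11.7 and 20.9 to 239.7, 222.5 and 153.9. The largest falls under the naming rule were in Umodl1 (−3.38, SE 0.84, adjusted p 0.0209), Ceacam20 (−3.34), Cmya5 (−3.32), Irf1 (−3.30, SE 0.43, adjusted p 0.00142), Rfpl4b (−3.25), Fam46b (−3.06), Cdo1 (−3.00), Angptl2 (−2.96), Lingo2 (−2.95), Efcab6 (−2.92), Slc30a1 (−2.90) and Gas2l3 (−2.78). Irf1 dropped from 73.9, 52.2 and 52.8 CPM to 8.34, 3.08 and 8.96. Pou5f1 fell by 1.10 on the log2 scale (adjusted p 0.00188). Klf2 (2.60), Hand1 (3.34), Tead4 (1.92) and Xist (2.21) rose, as did Dppa3 (0.83), Klf5 (1.15), Rhoa (1.12), Khdc3 (2.42), Ccnb1 (1.13), Cdc20 (1.58) and Cdk4 (2.08). Pard3 (−2.65), Pard6b (−1.89), Dab2 (−1.83), G6pdx (−1.93), Pkm (−1.56), Prdx2 (−2.37), Bcl2l1 (−1.67), Zfp57 (−1.26), Odf2 (−1.59), Rlim (−1.28) and Cnot7 (−1.07) fell, while Casp6 (3.16), Bax (1.24), Mcl1 (1.14), Gpx4 (1.44), Hspa8 (1.64), Hsp90ab1 (1.66), Hsp90aa1 (1.14), Hdac1 (0.88) and Mpc2 (1.28) rose.

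Set against other genes by limma's camera with a preset correlation, lists that passed at 4 cells were ribosomal proteins (adjusted p 2.42e-43, adjusted p with an estimated correlation 0.198), respiratory chain (1.78e-23, 0.198), nucleolar genes (8.78e-11, 0.0738), cell cycle (9.52e-06, 0.0738), 2-cell-stage activation (2.27e-07, 0.162) and oocyte-deposited transcripts (0.000358, 0.698). No list held with an estimated correlation. Cell cycle genes had 16 rises of 38 and 0 falls (22 and 2 adjusted over the list alone, median 0.49), and oocyte-deposited transcripts 3 rises and 2 falls of 37 (3 and 1 adjusted over the list alone, median −1.16). Lists that did not pass, with rises and falls past the threshold and the camera adjusted p, were the AHR pathway (5 and 1, 0.431, median −0.05 but mean 0.56), pluripotency (6 and 3, 0.431), trophectoderm (4 and 3, 0.846, median −0.04 against a camera sign upward), Hippo and polarity (3 and 7, 0.621), glycolysis (5 and 5, 0.68), p53 targets (4 and 2, 0.854, median 0.14, mean −0.02), NRF2 (7 and 4, 0.681, median 0.26, mean −0.06), heat shock (3 and 6, 0.681, median −0.07, mean 0.04), chromatin regulators (5 and 2, 0.949, median and mean negative, camera sign upward), apoptosis (9 and 2, 0.0809), cumulus, oviduct and blood (0 and 0 each, 0.506), sperm (0 and 1, 0.431) and X and Y genes (1 and 1, 0.782, median −0.23, mean 0.06). Adjusted over the list alone, those with other counts were pluripotency (7 and 3), Hippo (4 and 8), glycolysis (6 and 6), NRF2 (9 and 4), heat shock (4 and 7) and apoptosis (10 and 4). The median of all tested genes was −0.08 with TMM, −0.18 with DESeq2 size factors and −0.29 with the mean CPM per blastomere, and under the last the medians of pluripotency (−0.13), NRF2 (−0.15) and p53 targets (−0.25) turned negative. Among calls, 68.4% were rises with TMM and 31.9% with the mean CPM (limma), where 2072 rose and 4428 fell.

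From the 4-cell to the 8-cell stage, genes of both early lineages rose together. Pou5f1 rose by 4.33 (adjusted p 3.81e-05), Tfcp2l1 by 5.09 and Tbx3 by 3.73 among 13 of 21 pluripotency genes, while Fgf4 fell by 2.53 as the single fall (14 and 1 adjusted over the list alone, list median 2.03). Dab2 (4.94), Fgfr2 (3.92), Klf5 (1.67) and Ly6a (7.73) were among 14 of 21 trophectoderm genes that rose, with 3 falls (the same adjusted over the list alone, median 1.75). Cdh1 (3.64), Pard6b (3.06) and Ctnna1 (2.49) rose and Rock1 (−1.85) fell in the Hippo, polarity and compaction list, 14 rises and 4 falls of 28 in both adjustments. Genes of 2-cell activation fell further, 22 of 27 with 2 rises in both adjustments and a median of −4.78, as did 25 of 37 oocyte-deposited transcripts with 1 rise (26 and 1 adjusted over the list alone, median −2.95). The summed level of the activation list per blastomere did not fall in each condition. In wild type, dioxin and labelled knockout its medians were 3378, 3014 and 2869 CPM at 4 cells and 2648, 2277 and 3161 at 8 cells. With TMM scaling they were 3478, 2948 and 2727, and 3856, 3076 and 4011.

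In all 7056 genes passed, 3546 rising and 3510 falling, 5527 of them at least 2-fold. Under the naming rule Apoa1 rose most (10.2, SE 1.13, adjusted p 0.000374), from at most 0.07 CPM to 58 in wild type, 93.4 in dioxin and 16.1 in the labelled knockout. Other large rises were in Ly6a (7.73), Nek6 (7.63), Perp (7.63, SE 0.50, adjusted p 7.57e-05), Vangl1 (7.01), Crip2 (6.53, SE 0.37, adjusted p 6.64e-05), Cdyl2 (6.36), Lasp1 (6.07), Dap (6.06), Vnn1 (5.98) and Akr1b8 (5.90). Perp encodes a desmosome protein. The largest falls under the naming rule were in Zfp352 (−8.86, SE 0.45, adjusted p 3.81e-05), Creld1 (−7.54), AA543401 (−7.29), Fam43b (−6.67), AU015228 (−6.37), Mfsd2a (−6.33), Tnfaip8l2 (−6.02), Spesp1 (−5.91), Rfpl4b (−5.80), Chrna10 (−5.20), AA415398 (−5.14) and Mmp19 (−5.00). Xist rose by 5.21 and Tsix by 4.86, while Uty fell by 2.75. Embryo sex was not among the labels used here. For X- and Y-linked genes, differing shares of each sex therefore cannot be told apart from stage, at this step or the one before. Among metabolic genes Pdha1 (2.73), Hk1 (2.65), Sdha (2.05) and Ndufs6 (3.04) rose and Ldhb (−3.44) fell; Hsp90aa1 (2.75), Hspa8 (2.80), Gsta1 (3.34), Gsto1 (5.87), Sod2 (1.43), Hdac3 (4.29), Dnmt3b (2.69), Ccng1 (4.26), Eda2r (6.42), Mcm5 (1.91), Ccnd3 (3.39), Bok (3.60), Npm1 (1.51), Rpl4 (1.88), Rpl7a (2.25), Khdc3 (4.26), Pcsk6 (4.23) and Tppp3 (1.90) rose. Arnt, the partner of the receptor, fell by 0.94 (adjusted p 0.0019), along with Gclc (−1.99), Dnajb9 (−1.96), Zfp57 (−3.12), Cdc25c (−1.91), Bid (−1.24), Polr1e (−1.47), Tle6 (−2.43), H1foo (−3.88), Obox3 (−8.23), Usp17lb (−5.08), Tnfaip6 (−5.57) and Cfap126 (−4.78).

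By camera at 8 against 4 cells, ribosomal proteins (78 rises, 1 fall in both adjustments, adjusted p 6.08e-29, adjusted p with an estimated correlation 0.483), respiratory chain (65 and 4, or 66 and 4 adjusted over the list alone, 1.79e-14, 0.483), oocyte-deposited transcripts (9.73e-07, 0.559), 2-cell activation (1.63e-05, 0.427), pluripotency (0.000256, 0.427), trophectoderm (0.000272, 0.535), Hippo (0.0192, 0.559) and nucleolar genes (19 and 6, or 20 and 6 adjusted over the list alone, 0.0289, 0.535) passed. None held with an estimated correlation. The remaining lists did not pass: AHR pathway (5 rises, 3 falls, camera adjusted p 0.552, median −0.31 but mean 0.22), glycolysis (10 and 6, 0.383), p53 targets (9 and 3, 0.149), NRF2 (10 and 5, 0.279), heat shock (5 and 5, 0.939, median 0.03, mean −0.04), chromatin (13 and 9, 0.276), cell cycle (12 and 9, 0.759, median −0.05, mean 0.08), apoptosis (9 and 5, 0.345), cumulus (2 and 1, 0.759), oviduct (1 and 1, 0.838, median 0.48, mean −0.30), blood (0 and 0, 0.53), sperm (0 and 0, 0.57) and X and Y genes (2 and 3, 0.759). Adjusted over the list alone the counts that differed were glycolysis (11 and 6), p53 targets (10 and 3), chromatin (15 and 9), cell cycle (13 and 9) and X and Y genes (2 and 4). The median of all tested genes was −0.12 with TMM and −0.37 with the mean CPM per blastomere, under which chromatin (−0.19), glycolysis (−0.21), apoptosis (−0.06), heat shock (−0.42) and oviduct (−0.05) medians were negative and the share of rises was 32.8 in place of 50.3%.

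**Figure D2:**
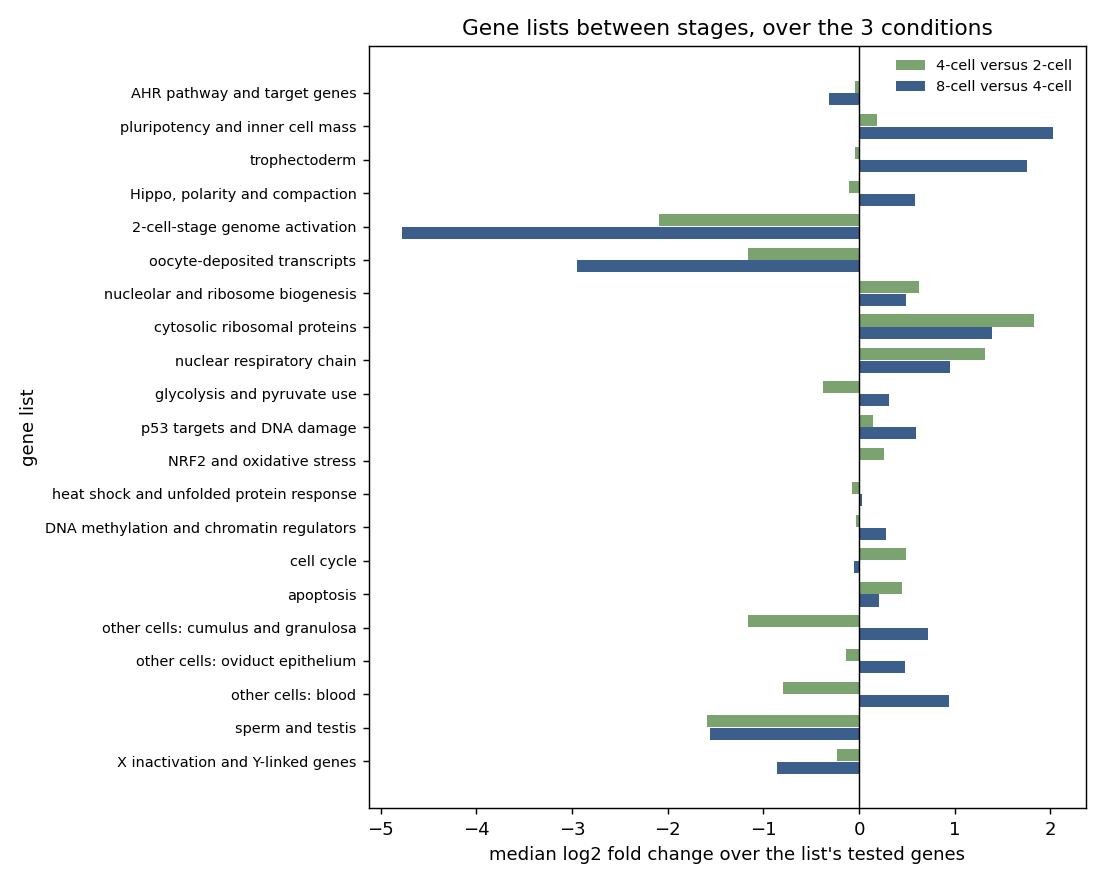
Bars give the median log2 fold change of each gene list's tested genes for 4-cell versus 2-cell and 8-cell versus 4-cell sums over the 3 conditions. Ribosomal proteins rise at both steps (1.83 and 1.39) and 2-cell-stage activation genes fall at both (−2.09 and −4.78).

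Between the labelled Ahr knockout and wild type over the stages, Crxos was the single gene that passed. It fell by 1.25 on the log2 scale (SE 0.11, edgeR adjusted p 0.0477), from 863, 2043 and 4666 CPM in wild type to 329, 862 and 2074 at 2, 4 and 8 cells. Dioxin stood at 803, 1605 and 4228. Crxos encodes a homeobox protein of early embryos. The Crxos call lay at the threshold: its adjusted p was 0.0551 with DESeq2 size factors, 0.0519 when thinned then summed, 0.813 without the 2-cell sums and 0.978 without the 4-cell sums, with log2 values of −1.20 to −1.29 when a stage was left out. In edgeR 1037 genes had an unadjusted p under 0.05. The limma-voom test gave 2 genes and the DESeq2 Wald test 67.

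Several lists were lower in the labelled knockout by camera, though 0 member genes passed over all genes in edgeR and no call held with an estimated correlation. Brackets give the list median, the camera adjusted p and the adjusted p with an estimated correlation, in that order. Ribosomal proteins were negative in 80 of 82 cases (median −0.31, adjusted p 1.02e-35, adjusted p with an estimated correlation 0.326), with Rpl41 at −0.31. Respiratory chain genes were negative in 73 of 82 (median −0.30, 1.2e-23, 0.326), 2 of them lower when adjusted over the list alone; Atp5g1 was at −0.50 (SE 0.12, adjusted p 0.679). Genes of 2-cell activation were negative in 24 of 27 (median −0.60, 3.91e-10, 0.261), and pluripotency genes in 16 of 21 (median −0.26, 0.000854, 0.261), with 1 pluripotency gene lower adjusted over the list alone. The summed activation level per blastomere was lower in the labelled knockout at 2 and 4 cells. At 8 cells it was higher, with medians of 3161 against 2648 CPM (4011 against 3856 with TMM scaling). Trophectoderm passed downward (0.0157, 0.47) although its median of 0.12 and mean of 0.17 were positive, the median being −0.05 with the mean CPM per blastomere; Klf5 was at −0.41 and Dab2 at −0.58. Heat shock genes (median −0.19, 0.0455, 0.538) had a median of 0.01 with the mean CPM; Hspa8 was at −0.42. Without the 8-cell sums the calls of pluripotency (adjusted p 0.378), trophectoderm (0.361, upward) and heat shock genes (0.922) ended. By fry, which asks whether genes move on balance one way, 2-cell activation and apoptosis passed (adjusted p 0.0428 each).

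The other lists did not pass by camera in this comparison. Their medians and camera adjusted p were AHR pathway −0.08 (0.223, mean 0.05), Hippo −0.08 (0.402, mean 0.03), oocyte 0.40 (0.351, mean 0.62 but a downward camera sign), nucleolar −0.07 (0.103), glycolysis −0.14 (0.154, mean 0.13), p53 targets 0.19 (0.199), NRF2 0.03 (0.161, mean −0.02, with 2 lower adjusted over the list alone), chromatin −0.07 (0.159), cell cycle −0.09 (0.181), apoptosis −0.13 (0.181, mean 0.06), cumulus 0.78 (0.181), oviduct 0.16 (0.223), blood 0.60 (0.159), sperm 0.52 (0.942, downward camera sign) and X and Y genes 0.10 (0.475). With the mean CPM per blastomere the medians of the nucleolar, chromatin, Hippo, cell cycle, apoptosis, glycolysis and sperm lists changed sign. Adjusted over the list alone, 0 genes passed in lists with no count given. Prdx2 was at −0.81, Prdx1 at −0.54, Pdha1 at −0.50, Hsp90aa1 at −0.46, Birc5 at −0.43, Npm1 at −0.34 and Tiparp at 1.04 (SE 0.68), all with edgeR adjusted p of 0.679 or more.

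At 2 cells the labelled knockout was lower in transcripts that the oocyte stores and in those of 2-cell activation. Of 37 oocyte-deposited transcripts 35 were lower, 14 at least 2-fold (median log2 ratio −0.83), among them Tcl1 at 407.4 (400.6 to 414.3) against 1893 (1877 to 1909) CPM. Of 27 activation genes 25 were lower, 14 at least 2-fold (median −1.14); both medians lay at percentile 0 of 10000 matched random lists, and both stayed negative with the mean CPM per blastomere (−0.51 and −0.78). The Zscan4 family, whose near-identical copies make single members uncertain, included Zscan4d at 80.3 against 157.3 and Zscan4a at 50.7 against 142.4 CPM. With libraries far from their stage left out in all conditions, medians were −0.57 for oocyte and −0.87 for activation genes.

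In brackets below, the log2 ratio follows the CPM of the 2 sums. By the rule of size 591 genes differed at 2 cells, 82 higher and 509 lower. The mean CPM per blastomere gave 268 and 215, and it also moved the median of all genes from −0.18 to 0.12. With far libraries left out 233 were higher and 234 lower. Highest were the co-chaperone gene Bag3 (55.7, 53.2 to 58.3, against 8.51, 7.49 to 9.64 CPM, log2 ratio 2.70), Acad8 (39.5 against 6.08, 2.69), Dgat2 (2.44), Aar2 (2.21), Plbd1 (2.19), Fig4 (2.10), Pdcd6 (2.06) and Mib1 (1.98). Lowest were Cd300lf (4.37 against 21.2 CPM, −2.27), Tcl1 (−2.22), Dbndd1 (−2.10), Lypd3 (−2.06), Grm2 (62.2 against 234.7 CPM, −1.91), Sepw1 (−1.91), Calml4 (−1.90) and Car9 (−1.89). Ribosomal (−0.12) and respiratory chain (−0.13) medians turned to 0.17 each with the mean CPM.

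At 4 cells the labelled knockout was lower in ribosomal protein genes (77 of 82, median −0.35) and respiratory chain genes (70 of 82, −0.39), and these medians were −0.03 and −0.02 when only wild-type blastomeres of title code 1 were used, but −0.68 and −0.71 with title code 3. The first number of the title code has the form of a plate position, which the labels do not explain, and all labelled-knockout 4-cell blastomeres have code 2, so code and label cannot be told apart here. The rule of size gave 257 genes, 130 higher and 127 lower, or 203 and 75 with the mean CPM per blastomere, 132 in all with wild-type title code 1 and 1286 with code 3. Highest were BC048546 (71.3 against 1.48 CPM, 5.55), Parp8 (37.4 against 1.05, 5.10), Crip1 (40.1 against 2.03, 4.28), Ovgp1 (365.1, 359.5 to 370.8, against 25.1, 23.5 to 26.6, 3.86), Slc26a4 (3.21), Tmsb4x (2.89), Gadd45a (2.23) and Igdcc3 (2.13). Medians and maxima per labelled-knockout blastomere were 15.7 and 8558 CPM in Ovgp1, 0.82 and 1757 in BC048546, 2.54 and 929.5 in Crip1 and 9.42 and 953.3 in Tmsb4x. Wild-type medians of Crip1 and Tmsb4x were 0 and 3.95. Without far libraries Crip1 was at 1.67, Tmsb4x at 1.89 and Ovgp1 at 3.89. Parp8 had a median of 21.8 and Slc26a4, which lies within 20 Mb of Ahr, of 23.7 CPM against 0 in wild type. Lowest were Tex101 (1.47 against 40.7 CPM, −4.75), Fbp2 (3.61 against 45.8, −3.65), Idh1 (5.97 against 49.2, −3.03), Acadl (−2.35), Rap2c (−2.16), Cish (−2.12), Atp6ap1l (−2.11) and Rpain (−2.04). The wild-type median of Tex101 was 1.08 CPM. With wild-type title code 1 alone, Tex101 was at −0.64, Fbp2 at −2, Idh1 at −1.48, Acadl at −0.69, Atp6ap1l at −1.41, Rap2c at 0.05 and Ovgp1 at 7.17.

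At 8 cells most listed genes of both lineages were lower in the labelled knockout. Of 21 trophectoderm genes 17 were lower, 8 at least 2-fold (median −0.88): Gata3 at 23.9 (22.8 to 24.9) against 61 (59.2 to 62.8) CPM, Eomes at 6.97 against 21.3, Krt8 at 42.4 against 81.5, Krt18 at 60.9 against 139.0 and Ly6a at 90.7 against 265.4, while Tead4 (186.0 against 173.8) and Tfap2c (286.5 against 308.8) were close. The summed pluripotency level per blastomere had a median of 8378 against 8186 CPM before TMM scaling, higher in the labelled knockout, and of 10630 against 11920 after it. Of 21 pluripotency genes 17 were lower (median −0.59), Klf4 at 34.3 against 78.7, Zfp42 at 104.7 against 180.3, Tfcp2l1 at 183.2 against 358.5 and Nanog at 30.2 (29 to 31.4) against 50.4 (48.8 to 52) CPM. A Nanog read was found in 84.7 against 96.4% of blastomeres at equal depth, the same unthinned, and a Sox2 read in 3.4 (0.4 to 11.7) against 21.8% (11.8 to 35, 5.1 and 21.4% unthinned). Ribosomal and respiratory chain medians were both −0.53. These 4 medians kept their sign with the mean CPM per blastomere (−0.45, −0.40, −0.33 and −0.31) and with libraries far from their stage left out (−0.71, −0.41, −0.37 and −0.36). Markers of other cells also differed. Oviduct markers were at least 2-fold higher in 7 of 11 genes and lower in 3 (median 1.26, or 0.66 with the mean CPM), but their summed level per blastomere had a median of 80.25 against 225.3 CPM (101.8 against 328 with TMM scaling), in which Epcam weighs most (sums of 95.6 against 352.8). Cumulus markers had a median of −0.21 (−0.205), while their summed level had a median of 34.8 against 18.3 CPM, with 7 of 59 blastomeres above the wild-type maximum (44.2 against 26.7 and 4 with TMM scaling). Much of that labelled-knockout level came from a single list member, Pcsk6, so it says little on the other markers. Blood markers (3 of 4, median 1.26) and X and Y genes (6 of 10, median 1.55) were higher. For the X and Y genes, the unlabelled sex of the embryos cannot be told apart from condition. The summed level of blood markers lay near 0 in both groups, with medians per blastomere of 2.21 against 0.76 CPM.

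Oocyte-deposited transcripts went the other way at 8 cells: 32 of 37 were higher in the labelled knockout, 21 at least 2-fold (median 1.22), with Btg4 at 339.6 against 3.74 CPM, Bmp15 at 177.1 against 1.20, Wee2 at 112.4 against 0.0963 and Omt2a at 121.7 against 9.42. Much of this went with few libraries: those with title codes 3A3 and 3F2 correlated at 0.293 and 0.272 with the 8-cell profile, and over genes seen across stages at 0.428 and 0.430 with the 2-cell, 0.279 and 0.271 with the 4-cell and 0.172 and 0.150 with the 8-cell profile. With the far libraries left out the median was 0.17, above the 0.10 that bounds matched random lists. The list's summed level per blastomere had quartiles of 3990, 4259 and 4600 CPM against 3272, 3646 and 3966 in wild type before TMM scaling, and 5064, 5405 and 5838 against 4764, 5308 and 5775 after it. Ccnb1 weighs most in that sum, with medians of 2801 against 1838 CPM before TMM scaling. Khdc3, also a large part, went the other way (755.7 against 1104). Without far libraries most of the highest genes also came close to wild type, Trim61 (402.2 against 2.57 CPM, 7.27, or 0.57 without far libraries), C86187 (6.35, −0.43), Zbed3 (553.9 against 6.86, 6.33, −0.34), Map1b (4.69, 2.80), Pkd2l2 (4.41, −0.36), Lrrfip1 (4.32, 0.75), Rrm2b (92.4 against 4.88, 4.23, 0.61) and D1Ertd622e (4.22, 1.95). Tiparp, a direct receptor target, had a sum of 583.5 against 86.7 CPM but medians per blastomere of 69.2 and 39.7. The lowest genes kept their size without far libraries: Ptges (19.7 against 105.2 CPM, −2.41, or −2.23), Tet2 (23.5 against 116.7, −2.31, or −2.14), Gss (13.5 against 62.4, −2.20, or −2.02), Trp53bp2 (−2.13), Phlda1 (−2.13), Pfkfb4 (−2.08), Tspan3 (−2.06) and Sdc4 (−2.01). The rule of size gave 368 genes, 151 higher and 217 lower, or 210 and 82 with the mean CPM, 56 and 137 (193 in all) with far libraries left out and 592 with no blastomere filter. Wild-type 8-cell blastomeres all have title code 2 and no labelled-knockout library in the sums shares it, so code and label cannot be told apart.

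Dioxin and wild type differed in 0 genes over the stages by edgeR, with 168 at an unadjusted p under 0.05; limma-voom also gave 0 and the DESeq2 Wald test 11. The clearest list was 2-cell activation, negative in 24 of 27 genes (median −0.32) by camera (adjusted p 5.07e-17, adjusted p with an estimated correlation 0.0142) and fry (0.0269), the one call that held with an estimated correlation. In the same order as above, genes of p53 and DNA damage were positive in 21 of 27 (median 0.46, 5.06e-11, 0.217), with Mdm2 at 0.82 and Cdkn1a at 0.60. Blood (median 1.17, 0.00778, 0.217, Alas2 at 2.88) and oviduct markers (1.07, 0.0116, 0.504, Ovgp1 at 1.45) were higher; respiratory chain (−0.10, 2.51e-06, 0.504), ribosomal (−0.10, 4.16e-06, 0.586), nucleolar (−0.09, 0.000566, 0.217), cell cycle (−0.08, 0.00263, 0.217) and pluripotency genes (−0.08, 0.0349, 0.446) were lower. With the mean CPM per blastomere these 5 medians were −0.02 (−0.021), −0.02 (−0.016), −0.01 (−0.005), −0.02 (−0.024) and 0.00 (0.001). Without the 8-cell sums the calls of p53 targets (0.333), blood (0.333), oviduct (0.203, downward), nucleolar (0.236), cell cycle (0.278) and pluripotency genes (0.913, upward) ended. The oviduct medians were 0.06 at 2, −1.85 at 4 and 4.53 at 8 cells.

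The AHR pathway list did not pass for dioxin (median −0.04, mean 0.06, camera adjusted p 0.498). Cyp1a1, the classical target, had 4, 66 and 11 reads in the dioxin sums at 2, 4 and 8 cells and 0 in wild type, found in 12.5, 5.9 and 1.6% of dioxin blastomeres. Cyp1b1 was at 0.40, 1.55 and 0.45 CPM in dioxin against 0.69, 0.63 and 0, Nqo1 at 9.18, 4.72 and 1.51 against 12.4, 3.16 and 2.12, and Tiparp at 659.3, 293.2 and 67.8 against 761.2, 261.7 and 86.7. Other lists that did not pass, with median and camera adjusted p, were trophectoderm (0.04, 0.282), Hippo (−0.05, 0.308), oocyte (−0.18, 0.0588), glycolysis (−0.12, 0.214, mean 0.04), NRF2 (−0.05, 0.248, mean 0.03), heat shock (−0.00, 0.528, mean 0.05), chromatin (−0.07, 0.0683), apoptosis (−0.04, 0.308, mean 0.16), cumulus (−0.78, 0.214), sperm (0.04, 0.553, mean −0.79) and X and Y genes (0.06, 0.605). The medians of AHR, NRF2, chromatin, Hippo, apoptosis and heat shock lists turned positive with the mean CPM. In each list 0 genes passed, also adjusted over the list alone. Both conditions were compared with the same wild-type sums, so likeness between these comparisons is in part shared.

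At 2 cells, all from title code 1, dioxin was lower than wild type in 24 of 27 activation genes, 10 at least 2-fold (median −0.68, −0.34 without far libraries), with Zscan4f at 30.6 against 111.0 and Usp17lc at 59.6 against 123.6 CPM. Oocyte-deposited transcripts were lower in 33 of 37 (median −0.33), Tcl1 at 733.8 against 1893 CPM (log2 ratio −1.37). The rule of size gave 73 genes, 14 higher and 59 lower, against 28 (17 and 11) with far libraries left out and 120 thinned then summed. Tmsb4x (64.2 against 15.7 CPM, 2.03), Nup62cl (1.71), Isg20 (1.69), Mcts1 (1.44), Gstm2 (55.3 against 21.2, 1.38), Fxyd4 (1.35), Zfp317 (1.31) and Gstm1 (1.31) were highest, and Tex101 (−1.96), AF067061 (−1.48), Tcl1, Sh3rf2 (−1.26), Fras1 (−1.22), Cd300lf (−1.21), Gpr35 (−1.21) and Slc5a3 (−1.17) lowest. Gstm2 (10.8 and 19.9 CPM) and Fxyd4 (8.46 and 10.7) had medians per blastomere opposite to their sums, and those of Gstm1 were 20.5 and 18.3.

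At 4 cells 38 genes differed by size, 17 higher and 21 lower (25 and 16 with the mean CPM per blastomere), but 87 with outside title codes left out and 746 with wild-type title code 3. Zfp282 (28 against 10.3 CPM, 1.43), Cdkn1c (45.7 against 17.9, 1.35), Gli3 (1.32), Lmf2 (1.24), Hspa1b (1.24), Tiam1 (1.21), Smad7 (1.20) and Entpd5 (1.17) were highest. Tex101 (3.13 against 40.7 CPM, −3.68), Idh1 (−2.27), Ovgp1 (6.90 against 25.1, −1.85), Zfp472 (−1.56), Zfp42 (18.9 against 45.2, −1.26), Tcp11l2 (−1.25), AI662270 (−1.25) and Fbp2 (−1.21) were lowest. Within title code 1 in both groups 28 genes differed, Ovgp1 was at 0.64, Tex101 at −0.51, Fbp2 at −0.18 and Idh1 at −1.08. With wild-type code 1 alone Ovgp1 was at 1.45, Tex101 at 0.43, Fbp2 at 0.44 and Idh1 at −0.72. Activation genes were lower in 24 of 27 (median −0.49, or −0.44 within code 1). Ribosomal (−0.19) and respiratory chain (−0.23) medians were 0.08 and 0.06 within code 1.

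At 8 cells dioxin sums were higher in p53 targets: 20 of 27, 14 at least 2-fold (median 1.27), with Cdkn1a at 517.3 (511.9 to 522.7) against 133.4 (130.8 to 136.1) CPM, Mdm2 at 270.2 against 76.9, Ccng1 at 240.9 against 64.3, Plk2 at 199.2 against 33.8, Phlda3 at 96.7 against 11.2 and Btg2 at 35.5 against 5.60. The excess was uneven: the list's summed level had medians per blastomere of 1111 in dioxin and 984.1 CPM in wild type, 16 of 62 dioxin blastomeres lay above the wild-type maximum (1502 and 1433 CPM and 13 blastomeres with TMM scaling), and Mdm2 medians were 51.2 and 51.6 CPM. The list median was 1.47 in dioxin blastomeres of title code 3, 0.26 in those of code 4, and 1.07 without far libraries. Markers of oviduct epithelium were higher in 11 of 11 genes (median 4.53, or 0.85 with the mean CPM), with Ovgp1 at 116.5 (113.9 to 119.1) against 3.78 (3.35 to 4.26) CPM, in 98.4 against 37.5% of blastomeres, and Ltf at 18.7 against 0.77. Ovgp1 was at 148.1 CPM in title code 3 and 51.15 in code 4 before TMM scaling, and the list medians were 4.03 (4.035) and 4.13. Most other members lay near 0 in wild type, and the summed level per blastomere had a median of 344.8 against 225.3 CPM (465.8 against 328 with TMM scaling), with 8 of 62 above the wild-type maximum. Blood markers (4 of 4, median 2.48), NRF2 genes (18 of 25, 0.18) and the AHR list (11 of 16, 0.14) were also higher. The summed level of blood markers lay near 0 in most blastomeres, with medians of 2.98 against 0.76 CPM and 8 of 62 above the wild-type maximum.

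The rule of size gave 206 genes at 8 cells, 61 higher and 145 lower, or 59 and 56 with the mean CPM and 591 in all with dioxin title code 3. Highest were Prap1 (41.7 against 0.261 CPM, 7.11), Gstm1 (64.7 against 1.88, 5.07), Ovgp1 (4.93), Rtkn (4.33), Gstm2 (58.4 against 3.15, 4.20), Tmsb4x (3.84), Serpina1e (3.61) and Phlda3 (3.11); medians per blastomere were 1.34 in Prap1, 2.50 in Rtkn, 6.38 in Serpina1e, 26.1 in Gstm1 and 25.8 in Gstm2, each against 0 CPM. With dioxin blastomeres of title code 3 or 4 alone, Rtkn was at 5.48 and 0.87, and Prap1 at 3.93 with code 3 and higher with code 4. Lowest were Npc1l1 (8.93 against 45.6 CPM, −2.35), Bex1 (−1.99), Socs3 (35.8 against 140.6, −1.97), Ddx60 (−1.88), Ephb4 (−1.87), Kcnk5 (−1.70), Tmem229b (−1.66) and Sox21 (9.59 against 28.9, −1.58). A Sox21 read was found in 60.7 against 90.9% of blastomeres at equal depth (64.5 and 91.1% unthinned). Dioxin blastomeres here have title codes 3 and 4 and wild type code 2, so code and exposure cannot be told apart.

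**Figure D3:**
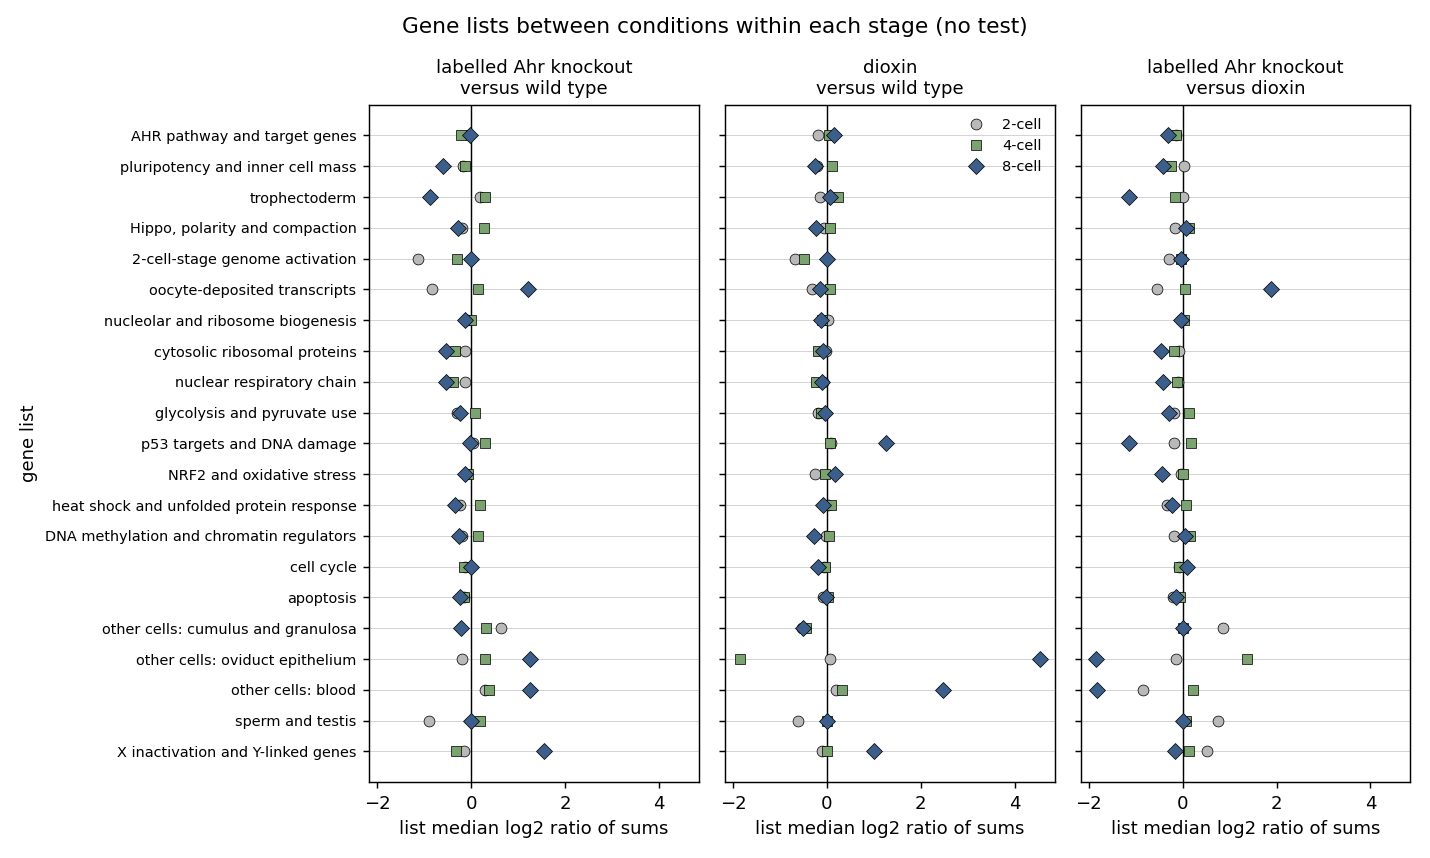
Points give each list's median log2 ratio between condition sums at 2, 4 and 8 cells, without a test. Oviduct markers stand at 4.53 and p53 targets at 1.27 for dioxin against wild type at 8 cells, and trophectoderm at −0.88 for the labelled knockout.

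Labelled knockout and dioxin differed in 0 genes over the stages by edgeR, with 681 at an unadjusted p under 0.05; limma-voom gave 0 and the DESeq2 Wald test 20. Ahr differed by 0.19 (SE 0.86, adjusted p 0.982). Lower in the labelled knockout by camera were ribosomal proteins (median −0.21, adjusted p 9.54e-27, adjusted p with an estimated correlation 0.41), respiratory chain (−0.18, 3.5e-14, 0.41), trophectoderm (−0.14, 0.000152, 0.41), p53 targets (−0.42, 0.000717, 0.41), heat shock (−0.17, 0.00519, 0.412) and NRF2 genes (−0.05, 0.0185, 0.524, 1 lower adjusted over the list alone). Cumulus and granulosa markers were higher (median 1.34, 0.00879, 0.41, fry 0.00106), but not alike at each stage. Their summed level per blastomere had medians of 17.07, 2.825 and 34.84 CPM in the labelled knockout at 2, 4 and 8 cells. In dioxin these were 12.84, 4.997 and 10.76 CPM, so the 4-cell difference went the other way. Much of the 8-cell level in the labelled knockout came from Pcsk6 alone, whose 8-cell sums are given below. Without the 8-cell sums the calls of respiratory chain (0.122), trophectoderm (0.818, upward), p53 targets (0.533, upward), heat shock (0.533) and NRF2 genes (0.683) ended. By stage the medians were 0.00 (0.004), −0.16 and −1.15 for trophectoderm (−1.145) and −0.18, 0.17 and −1.15 for p53 targets (−1.149). No call held with an estimated correlation, and 0 member genes passed otherwise. Lists that did not pass, with median and camera adjusted p, were AHR pathway (−0.12, 0.104), pluripotency (−0.12, 0.055, mean 0.02), Hippo (0.06, 0.872), 2-cell activation (−0.00, 0.837), oocyte (0.49, 0.741), nucleolar (−0.01, 0.75, mean 0.01), glycolysis (−0.06, 0.737, mean 0.09), chromatin (0.02, 0.872, downward camera sign), cell cycle (0.02, 0.645), apoptosis (−0.06, 0.644), oviduct (−0.36, 0.75), blood (−0.66, 0.741), sperm (0.29, 0.75) and X and Y genes (0.13, 0.75). The nucleolar, glycolysis, apoptosis, 2-cell activation and sperm medians changed sign with the mean CPM.

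At 2 cells the labelled knockout was lower than dioxin in 34 of 37 oocyte-deposited transcripts (median −0.54). The rule of size gave 208 genes, 50 higher and 158 lower, against 132 and 58 with the mean CPM per blastomere and 66 and 122 with DESeq2 size factors, and 207 and 157 with far libraries left out. Bag3 (55.7 against 11.8 CPM, 2.24), Kcnk5 (44.6 against 9.62, 2.21), Mixl1 (1.98), Acad8 (1.98), Gca (1.94), Map1s (1.73), Cyp2s1 (1.70) and Aar2 (1.64) were highest. Fxyd4 (2.05 against 30.7 CPM, −3.88), Serpina1e (−3.45), Tmsb4x (−2.90), Gstm2 (7.78 against 55.3, −2.82), Gstm1 (−2.48), St6gal1 (−1.67), Calb1 (−1.65) and Zfp616 (−1.54) were lowest. Medians per blastomere were 7.07 against 10.8 CPM in Gstm2, 1.13 against 2.61 in Serpina1e, 9.22 against 20.5 in Gstm1 and 0.342 against 8.46 in Fxyd4. At 4 cells 117 genes differed, 62 higher and 55 lower: Ovgp1 (5.72), BC048546 (5.56), Parp8 (5.01), Crip1 (3.27, or 0.52 without far libraries), Tmsb4x (3.04), Gadd45a (2.41), Slc26a4 (1.92) and Itgal (1.73) against Nptx2 (5.77 against 28.5 CPM, −2.30), Cep135 (−2.24), Tdgf1 (28.4 against 118.9, −2.06), Fabp3 (−2.01), Smpdl3a (−1.82), Cish (−1.82), Reep1 (−1.76) and Atp6v0a4 (−1.47). All labelled-knockout blastomeres here have title code 2, while 30 dioxin blastomeres have code 1 and 4 have code 2. Code and label can thus hardly be told apart.

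At 8 cells the labelled knockout was lower than dioxin in trophectoderm genes (18 of 21, 11 at least 2-fold, median −1.15), p53 targets (22 of 27, −1.15), oviduct markers (11 of 11, −1.85), NRF2 genes (15 of 25, −0.44), ribosomal proteins (79 of 82, −0.46) and respiratory chain (74 of 82, −0.41). Within title code 3 in both groups, the medians were −0.78 for trophectoderm, −2.07 for p53 targets and for oviduct markers, and −0.26 for ribosomal proteins. Oocyte-deposited transcripts were higher (32 of 37, median 1.89, or 0.59 without far libraries). Among 533 genes by size, 290 higher and 243 lower (300 and 154 with the mean CPM, 524 and 281 within title code 3), Trim61 (7.90), Zbed3 (7.07), C86187 (6.67), Rrm2b (4.92), Pkd2l2 (4.56), Specc1l (3.63), D7Ertd443e (3.62) and Pcsk6 (40.6 against 3.29 CPM, 3.61) were highest. Without far libraries Trim61 was at 1.75, Rrm2b at 1.19, Zbed3 at 0.36, C86187 at 0.49, Pkd2l2 at −0.08 and Specc1l at 0.70, while Pcsk6 was at 3.56. Lowest were Rtkn (−4.17), Prap1 (−3.60, or −0.68 within title code 3), Sdc4 (13.9 against 148.1 CPM, −3.41), Phlda3 (−3.31), Btg2 (−3.12), Cryab (−2.93), Apoa1 (16.1 against 93.4, −2.53) and Gss (−2.50).

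**Figure D4:**
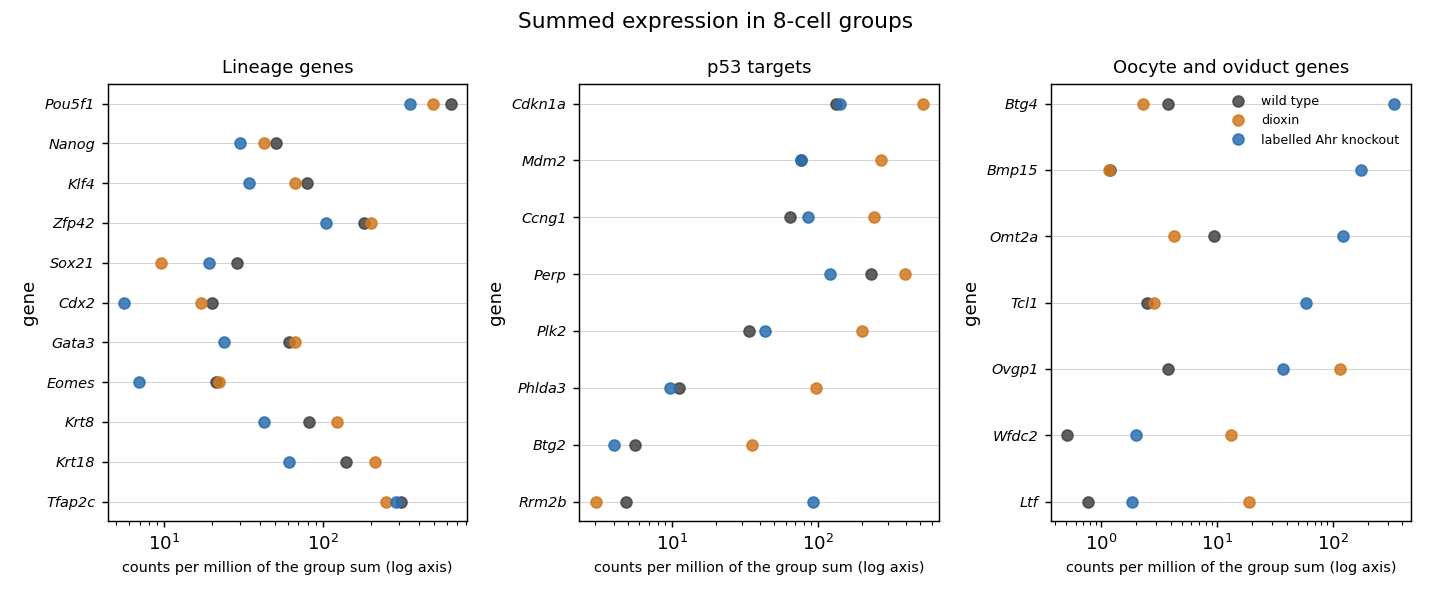
Points are CPM of the 8-cell group sums on log axes for lineage genes, p53 targets, and oocyte and oviduct genes in the 3 conditions. Gata3 (23.9 against 61) is lower in the labelled knockout than in wild type, and Cdkn1a (517.3 against 133.4) is higher in dioxin.

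Variation between blastomeres did not rank the conditions in 1 order: the labelled knockout was highest at 2 cells and lowest at 4 cells, and at 8 cells wild type was lowest. At 4 cells the wild-type value pools mainly title codes 1 and 3, while all labelled-knockout blastomeres have code 2. Far libraries were part of the 2-cell wild-type and labelled-knockout groups, among them 1G5 of the labelled knockout with 22070 genes detected. The median squared coefficient of variation at equal depth was 0.198, 0.171 and 0.222 in wild type, dioxin and labelled knockout at 2 cells over 7833 genes, 0.295, 0.256 and 0.192 at 4 cells over 7052, and 0.253, 0.326 and 0.346 at 8 cells over 6414; without far libraries the 8-cell values were 0.252, 0.285 and 0.283, and differences were not tested. On the way from 2 to 8 cells, the 4-cell sum lay at 0.420 in wild type (3861 genes), 0.366 in dioxin (4146) and 0.356 in the labelled knockout (5735). Wild-type 4-cell blastomeres of title code 1 lay at 0.358 and those of code 3 at 0.540, and these groups differed from each other in 970 genes by size (616 higher and 354 lower in code 1), more than any condition did from the full wild-type sum of a stage. The 4-cell count of the labelled knockout against wild-type code 3 alone, given above, was larger, so this ranking holds only for the full sums. Dioxin 8-cell blastomeres of codes 3 and 4 differed in 190 genes.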

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

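The tests of title code (whole and part), of dioxin at each stage, of most blastomeres (both forms), of an earlier stage and of developmental time were chosen only after the result was seen; those of oviduct RNA, few libraries, depth and splits were written before. The test of dioxin at each stage was first decided by −1.854 alone and counted against that explanation; it was then decided within title code 1, with that value already known.

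Positive controls, which no comparison used, had a median of 1393339 reads. The following log2 ratios changed direction between stages, and these differences were not tested. For labelled knockout against wild type, the highest and lowest values over stages were 3.86 and −1.34 in Ovgp1, 6.35 and −1.59 in C86187, 4.41 and −1.41 in Pkd2l2, and 1.70 and −2.20 in Gss. For dioxin against wild type Ovgp1 stood at 4.93 and −1.85. For labelled knockout against dioxin they were 3.04 and −2.90 in Tmsb4x, 1.31 and −2.48 in Gstm1, 5.72 and −1.64 in Ovgp1, 3.27 and −1.84 in Crip1, 6.67 and −1.01 in C86187, and 1.44 and −2.50 in Gss.

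Oviduct markers were higher in dioxin than in wild-type 8-cell blastomeres. If the RNA came from oviduct cells around the embryos, markers could be expected to keep their ratio to Ovgp1 between title codes; the median difference was 1.208, past the bound of 1 written before, but only Wfdc2 and Ltf could be measured, so this cannot tell. A title code block as the whole cause would put the labelled knockout near dioxin within title code 3, but it lay at −2.065. This argues against a block only if the knockout label itself leaves the list unchanged, which cannot be checked without wild type of code 3. As part of the difference a block cannot be told apart from exposure. The labelled knockout, mostly of code 3, lay at 1.263 relative to wild type, all of code 2. Its summed level per blastomere, in which Epcam weighs most, was lower (median 80.25 against 225.3 CPM). Ovgp1 stood at 148.1 CPM in dioxin code 3 against 51.15 in code 4. A rise caused by dioxin at each stage, the biological explanation, cannot be decided: the lowest list median was −1.854 at 4 cells, but it was 0 with title code 1 only in both groups and 0.609 with wild-type title code 1. What stays open is whether dioxin raises these transcripts, at 8 cells or at each stage, whether title code makes or adds to the difference, or whether oviduct RNA was carried over.

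Oocyte-deposited transcripts were higher in labelled-knockout than in wild-type 8-cell blastomeres. With a few libraries far from their stage left out the median was 0.171, above the 0.102 reached by matched random lists, so this cannot tell, as the excess shrank but did not end. A higher level in most labelled-knockout blastomeres, the biological explanation, was first tested over all members and gave 0. Of 37 members 24 were under 1 CPM in the median blastomere of both groups. After that result was seen the test was rewritten over the 13 others and gave 0.374 (9 higher, 4 lower), and both forms cannot tell. The summed level per blastomere was higher before TMM scaling (median 4259 against 3646 CPM) and nearly alike after it (5405 against 5308). Ccnb1 weighs most in that sum (medians of 2801 against 1838 CPM before TMM scaling), while Khdc3 went the other way (755.7 against 1104). Both also rose from 2 to 4 cells, so the sum says little on the other members. Blastomeres of a labelled earlier stage are argued against, since 0 of 2 libraries reached the lowest 5% of an earlier stage (0.859 at 2 and 0.847 at 4 cells), although both correlated better with the 2-cell (0.428 and 0.430) and 4-cell (0.279 and 0.271) than with the 8-cell profile (0.172 and 0.150). The nature of those 2 libraries, damaged or mixed earlier material included, stays open, as does the source of the Ahr reads at 4 and 8 cells, which go against a full loss of the transcript.

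Wild-type 4-cell blastomeres of title codes 1 and 3 differed in more genes than conditions did in the full sums. Against wild-type code 3 alone, the labelled knockout differed in more genes still. A difference in depth is argued against by 992 genes after thinning. A difference in developmental time, the biological explanation, is consistent with code 3 lying 0.182 further from the 2-cell toward the 8-cell level. Whether code stands for plate, litter or time of collection stays open.

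Splits of the 6 sums in each comparison numbered 10, too few for a share under 0.05. The real count and the highest other were 1 and 0 for labelled knockout against wild type, 0 and 1 for dioxin against wild type, 0 and 1 for labelled knockout against dioxin, 4165 and 0 for 4 against 2 cells, and 7056 and 0 for 8 against 4 cells. As many genes as in the real grouping were reached by 1, 10, 10, 1 and 1 of the 10 splits. These numbers include the real split, and a real count of 0 is reached by every split whatever the data. In the stage comparisons each other split puts sums of both stages on both sides, so its count of 0 says little.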

How the results depend on the processing

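The tests with far libraries left out and with wild-type 4-cell or dioxin 8-cell title codes taken singly were chosen only after the result was seen. Of 276 planned main values 213 stayed the same, and of 57 added ones 48 did; of 2503 and 453 values of named genes and lists, 2388 and 411 stayed and 10 and 8 reversed. The cause was not tested for any of the following. Depth limits scarce genes, as the labelled-knockout 2-cell sum of Ahr rests on 19 reads. At 2-fold the test recovered 24% of simulated genes, and whether depth or the few sums set this was not tested.

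Labelled knockout against wild type gave 0 genes with DESeq2 size factors, with 10 CPM in 3 sums, thinned then summed, with outside title codes left out, with no replicate block, with only the 6 sums compared, and with wild-type 4-cell title code 1 or 3 only; it gave 2 by limma-voom, 67 by the DESeq2 Wald test, and 0 to 1 in leave-one-out. The Wald test gave 11 for dioxin against wild type and 20 for labelled knockout against dioxin. For 4 against 2 cells the mean CPM per blastomere in limma gave 6500, only the 6 sums compared 6344, and leave-one-out 720 to 5281; for 8 against 4 cells leave-one-out gave 3431 to 7636. Without the block 4715 and 7536 genes passed between stages.

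Genes by size at 2, 4 and 8 cells with a minimum of 5 CPM were 1302, 672 and 700 for labelled knockout against wild type, 303, 265 and 419 for dioxin against wild type, 636, 384 and 946 for labelled knockout against dioxin, 1996 between wild-type title codes and 548 between dioxin title codes. With a minimum of 100 CPM they were 161, 46 and 91, 22, 2 and 47, 37, 15 and 123, 239 and 27. Labelled knockout against wild type at 8 cells gave 592 with no blastomere filter, 197 with the 2 MAD filter and 193 with far libraries left out; at 4 cells it gave 132 with wild-type title code 1 and 1286 with code 3. Dioxin against wild type gave 120 thinned then summed and 28 with far libraries left out at 2 cells; 87 with outside title codes left out and 746 with wild-type title code 3 at 4 cells; and 115 with the mean CPM and 591 with dioxin title code 3 at 8 cells. Labelled knockout against dioxin gave 364 with far libraries left out at 2 cells and 805 within title code 3 at 8 cells.

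Values that reversed at 8 cells with the 2 MAD filter and with far libraries left out were C86187 (−0.39 and −0.43), Zbed3 (−0.30 and −0.34) and Pkd2l2 (−0.34 and −0.36) against wild type, and Pkd2l2 against dioxin (−0.04 and −0.08). At 4 cells Ovgp1 for dioxin was 0.64 within title code 1 in both groups and 1.45 with wild-type title code 1, with which Tex101 (0.43), Fbp2 (0.44) and, for the labelled knockout, Rap2c (0.05) also reversed. Gene lists past the threshold numbered 0, 1 and 0 with an estimated correlation and 2, 1 and 1 by fry for labelled knockout against wild type, dioxin against wild type and labelled knockout against dioxin, and 5 to 8, 4 to 10 and 3 to 8 in leave-one-out. In leave-one-out the camera adjusted p ran from 0.00161 to 0.361 for trophectoderm in labelled knockout against wild type, 0.00594 to 0.913 for pluripotency and 2.59e-06 to 0.203 for oviduct in dioxin against wild type, and 7.01e-06 to 0.818 for trophectoderm and 6.24e-07 to 0.533 for p53 targets in labelled knockout against dioxin. Each highest value came without the 8-cell sums, where the direction reversed. With a mean thinned count of at least 50, the squared coefficient of variation in wild type, dioxin and labelled knockout was 0.122, 0.097 and 0.130 at 2 cells, 0.150, 0.128 and 0.098 at 4 cells, and 0.124, 0.156 and 0.181 at 8 cells.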

Other observations

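None of the tests in this part was chosen only after the result was seen, but Xist, Ahrr and Nanog were singled out after their values were seen, and differences between groups were not tested. Xist stood at 224 CPM in wild-type, 80.2 in dioxin and 170 in labelled-knockout 8-cell sums, with a read in 98.2, 51.6 and 78.0% of blastomeres. Embryo sex was not among the labels used here, so differing shares of each sex cannot be told apart from condition for Xist. Nnt, a strain marker in which some C57Bl/6 stocks carry a deletion, had 382, 315 and 156 reads in the wild-type, dioxin and labelled-knockout 8-cell sums. Nanog had a read in 50, 0 and 25% of wild-type, dioxin and labelled-knockout 2-cell blastomeres at equal depth (56.2, 6.2 and 25% unthinned), where a count of 0 allows up to 23.1% by 3 counts of the total (exact binomial upper limit 24.7%), and Ahrr stood at 1.18, 0.0732 and 0.967 CPM at 8 cells. In the 2-cell labelled knockout 14 of 21 trophectoderm genes were higher than in wild type (median log2 ratio 0.20).

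Among 122 tested genes within 20 Mb of Ahr on chromosome 12 of mm10, 36, 35 and 41 were at least 2-fold apart between labelled knockout and wild type at 2, 4 and 8 cells, or 29.5, 28.7 and 33.6%, where matched random lists had medians of 24.6, 21.3 and 23.8% and the observed shares lay at percentiles 89, 97.9 and 99.3. In edgeR 18 of the 122 had an unadjusted p under 0.05, against 1037 of all 16225 tested genes. By the rule of size 6 counted at each stage, among them Acp1, Iah1 and Slc26a4 at 4 cells and Acp1, Bcap29, Snx13 and Zfp277 at 8 cells. The squared coefficient of variation of Pou5f1 at 8 cells was 0.0477 in wild type, 0.0738 in dioxin and 0.177 in the labelled knockout, and that of Cdx2 1.23, 1.09 and 2.93.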
